A study of Mus musculus with 12 samples.

How the data were processed

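Hippocampal RNA of male C57/BL/6N mice aged 8 to 10 weeks was measured on 12 Affymetrix arrays with biotin-labelled cRNA. Each array held a pool of RNA from 6 animals, and there were 3 arrays for naive mice and 3 for each of 3 times (0.5, 2 and 6 h) after trace fear conditioning. The labels number the arrays of a group from 1 to 3 but do not say whether they held separate pools.

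The deposited values are probe set signals, an intensity on a linear scale made by the authors with MAS5, per the submitters' processing notes; the software version and settings are not stated. The values were checked to be linear, with maxima between 3552.6 and 4677.3 per array. The trimmed mean of each array, with 2% left off at each end, was 100.0, which is the scaling of the deposited table. Array medians lay between 36.1 and 37.8. No further normalization was applied. Detection calls were not available. The number of arrays limits the precision.

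A pseudocount of 1.9, the 10th percentile of all values, was added before taking log2, since 37 values were 0. Of 22690 probe sets, 64 control probe sets were left out, and of the others those at or above the 40th percentile of the mean log2 signal were tested, 13576 in all. Gene symbols came from the platform's probe table, updated through Entrez identifiers for 20364 probe sets. In that naming 20393 probe sets had 1 symbol, 691 had several, and 1555 besides the controls had none. The tested probe sets with 1 symbol numbered 12561 and covered 7860 genes. No genomic coordinates were used.

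A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 3.77 prior degrees of freedom). Each time after training was compared with naive, 2 h was compared with 0.5 h, 6 h was compared with 2 h, and a moderated F test asked for any difference among the 4 groups. P-values were adjusted with the Benjamini-Hochberg method over the tested probe sets, with a threshold of 0.05. All p-values are two-sided, and those of limma for probe sets measure only the spread between these arrays. No replicate block was used in the model, because the labels give no meaning to the replicate numbers.

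There were 34 lists, 19 of functional gene groups and 15 of markers of cell types or neighbouring regions. They were tested with camera of limma at a preset correlation between genes of 0.01, using for each gene the probe set of highest mean signal. Camera sets the statistics of a list against those of the other genes. At the preset value the correlation between genes is assumed and not measured from the arrays, so these p-values do not measure the spread between arrays alone. P-values were adjusted over the 32 lists with at least 4 measured members and the 3 comparisons with naive. Ependymal markers had 2 measured members and erythrocyte markers had 0, and neither list was tested. Camera was also run with a correlation estimated per list, and with fry, which asks whether the genes of a list move on balance in 1 direction. For each list the members past the threshold were counted over all tested probe sets and also adjusted over the list alone. The functional lists were immediate-early transcription factors, activity-induced effectors, glucocorticoid-responsive genes, circadian clock genes, glutamate receptors, GABA genes, postsynaptic density, synaptic vesicle, signalling by cAMP, MAPK and CREB, chromatin regulators, heat shock chaperones, endoplasmic reticulum chaperones, adhesion and guidance, neurotrophins and growth factors, voltage-gated channels, proteasome, cholesterol synthesis, ribosomal proteins and oxidative phosphorylation. The marker lists stood for astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, choroid plexus, ependyma, meninges, erythrocytes, thalamus, striatum, dentate granule, CA1 and CA3 neurons, and interneurons. Some genes are in several lists, so the list tests are not independent. Errfi1, Per1 and Cdkn1a are in the lists of activity-induced effectors and of glucocorticoid-responsive genes, and Per1 is also in the clock list.

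Genes were named by a rule. For each comparison with naive it took up to 12 genes per direction with the largest changes past the threshold and with the arrays of both groups not overlapping. Where fewer than 6 qualified, the list was filled to 6 by smallest unadjusted p among genes with non-overlapping arrays, given as not past the threshold. It added up to 4 members of each described list by absolute moderated t, and 15 genes listed whatever their values, of which Egr2 was too dim to be tested and Gdi1 was not in the probe table. Between times it took up to 6 genes per direction past the threshold. The groups, the model, the threshold, the lists, the naming rule and the first group of alternatives below were fixed before the data were examined.

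The procedure was tested on simulated data made from these arrays for the comparison of 0.5 h with naive. It recovered 21 of 67 probe sets (31.3%) with a true log2 change of 0.5, 61 of 67 (91.0%) with a change of 1 and 66 of 66 (100%) with a change of 2. Of its 154 calls, 6 were false. The simulated probe sets varied independently of each other. The real comparison gave 8 calls, so the adjusted threshold was easier to reach in the simulation. These shares therefore do not carry over to the real data, where fewer changes of a given size would pass.

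The alternatives tried were no pseudocount and a pseudocount of 7.6, no filter and a filter at the 60th percentile, quantile normalization and median centring, a variance trend with robust estimation, array weights, the replicate number as a block, each array left out in turn, only the 2 groups compared in the model, an adjusted p of 0.1, and an unadjusted p of 0.05 with at least a 1.5-fold change. Added after the data were seen were the log2 signal of the 18S ribosomal RNA control as a covariate, 2 or 3 arrays of highest 18S signal left out, and the list tests between times.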

Results

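The arrays measured gene expression in the hippocampus after trace fear conditioning, a form of learning in which a neutral stimulus and an aversive one are separated by an empty interval. There were 12 arrays in 4 groups of 3: naive mice, and trained mice whose hippocampi were collected 0.5 h, 2 h or 6 h after the procedure. The labels named no handled, context-only or time-matched control, so no difference from naive reported below, in activity-induced, glucocorticoid-responsive or other genes, can be assigned to the pairing of stimuli. Median signals were alike across arrays, from 36.1 to 37.8. The Spearman correlation between arrays was 0.966 to 0.985 within groups and 0.962 to 0.984 between groups. The log2 differences between 2 arrays of a group had an SD of 0.24 to 0.39. The first 2 principal components held 21.5% and 14.6% of the variance. The 18S ribosomal RNA control, a sign of RNA preparation, gave signals of 17.8 to 55.9 in naive arrays, 23.4 to 37.8 at 0.5 h, 25.9 to 642.5 at 2 h and 77.9 to 686.6 at 6 h. The 3 arrays of highest 18S signal, 2 h array 1 and 6 h arrays 2 and 3, lay highest on the first component, at 16.1, 17.1 and 15.2. The next array was at 5.23. Differences at 6 h are therefore partly confounded with that control. Errors of log2 changes below are standard errors of the limma model, and errors of signals are SDs, with n = 3 arrays per group throughout.

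The first comparison asked which transcripts differed from naive 0.5 h after training. The largest rises were in genes known to be induced by neuronal activity. Fos, a subunit of the AP-1 transcription factor, rose 5.80-fold, from a mean signal of 41.9 ± 8.71 in naive arrays to 249 ± 14.5 (log2 change 2.54 ± 0.13, adjusted p = 3.25e-06). Arc, a regulator of glutamate receptor traffic at synapses, rose 3.70-fold, from 75.8 ± 19.7 to 280.4 ± 36.8 (log2 change 1.89 ± 0.19, adjusted p = 0.00164). Dusp1, a phosphatase that switches off MAP kinases, rose 2.13-fold (log2 change 1.09 ± 0.11), and Junb, another AP-1 subunit, rose 1.98-fold (log2 change 0.99 ± 0.096), both with an adjusted p of 0.00164.

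The other rises at 0.5 h were smaller. The orphan nuclear receptors Nr4a1 and Nr4a2 rose 2.01-fold and 1.64-fold (log2 changes 1.01 ± 0.14 and 0.71 ± 0.094, adjusted p = 0.0271 and 0.0179). Gadd45b, a stress-response gene linked to DNA demethylation, rose 1.85-fold (log2 change 0.89 ± 0.13, adjusted p = 0.0370). Sgk1, a kinase induced by serum and glucocorticoids, rose 1.77-fold, from a signal of 423 ± 39.7 to 752 ± 79.7 (log2 change 0.82 ± 0.10, adjusted p = 0.0106). Egr1, a zinc finger transcription factor, went from 528 ± 36.3 to 869.9 ± 102 and did not pass (log2 change 0.71, adjusted p = 0.0689). The falls of smallest unadjusted p did not pass either: Fubp1 had a log2 change of -0.59 (adjusted p = 0.0854), Ttc28 of -0.52, Dhdds of -0.45, Bcar1 of -0.78, Nup93 of -0.41 and Trmt2a of -0.46. Bdnf, the brain-derived neurotrophic factor, was at 0.0031, and Homer1, a postsynaptic scaffold gene, was at 0.08. Of the rises in these genes, that of Gadd45b was lost in 16 of 24 other settings (adjusted p up to 0.243), among them the removal of any naive, 0.5 h or 2 h array or of 6 h array 2 or 3. Those of Nr4a1 (10 of 25, adjusted p up to 0.161), Nr4a2 (10 of 25, up to 0.213) and Sgk1 (7 of 25, up to 0.213) were each lost without naive array 1 or 3 or 0.5 h array 2 or 3, Nr4a1 and Nr4a2 also without 0.5 h array 1, and Nr4a1 also without naive array 2, 2 h array 3 or 6 h array 1 or 2.

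As groups, 7 of 32 lists had a call at 0.5 h with camera, and 2 of them, both of activity-induced genes, kept it with an estimated correlation. Of 18 immediate-early transcription factors, 3 rose by their brightest probe set (Fos, Junb and Nr4a1), Nr4a2 rose by another, which makes 4 by any probe set, and there were 7 rises adjusted over the list alone (median log2 change 0.29, adjusted p = 4.08e-14, and adjusted p = 0.0149 with an estimated correlation). Of 23 activity-induced effector genes, 2 rose by their brightest probe set (Arc and Dusp1), Gadd45b rose by another, which makes 3 by any probe set, and there were 7 rises adjusted over the list alone (median 0.19, adjusted p = 5.21e-10, and adjusted p = 0.0337 with an estimated correlation). Of 23 glucocorticoid-responsive genes, Sgk1 alone rose over all probe sets, and 5 rose adjusted over the list alone (median 0.075, adjusted p = 1.68e-05, but adjusted p = 0.0575 with an estimated correlation). Its other leading members were Errfi1 at 0.48, Plekhf1 at 0.51 and Nfkbia at 0.41, none past the threshold. Errfi1 is also in the list of activity-induced effectors. Single arrays moved 2 of these medians: that of activity-induced effector genes, 0.5 h against naive, was 0.11 without naive array 2, and that of glucocorticoid-responsive genes, 0.5 h against naive, was 0.12 and 0.13 without naive arrays 1 and 3, and 0.18 and 0.039 without 0.5 h arrays 2 and 3.

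Lists of markers of other tissue had calls at 0.5 h with camera, which were lost with an estimated correlation. All 11 choroid plexus markers had positive log2 changes (median 0.45, adjusted p = 3.3e-08, but adjusted p = 0.135 with an estimated correlation). Calml4 was at 0.48, Kl at 0.56, Sostdc1 at 0.45 and Cldn2 at 0.56. Of these markers, 0 passed in limma over all probe sets and 2 rose adjusted over the list alone. The 9 endothelial and mural markers had a median of -0.24 (adjusted p = 0.00154, but adjusted p = 0.225 with an estimated correlation), with Vtn at -0.37 and Slco1a4 at -0.26. Without 0.5 h array 3 that call was lost (endothelial and mural markers, 0.5 h against naive, median -0.11, adjusted p = 0.115).

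The 20 cytosolic heat shock chaperones had a median log2 change of 0.11 at 0.5 h (adjusted p = 0.000808, but adjusted p = 0.444 with an estimated correlation), and no member passed over all probe sets or adjusted over the list alone. Hspa1b was at 0.54, Dnajb1 at 0.39 and Hspb1 at 0.37. The 18 circadian clock genes had a median of 0.084 (adjusted p = 0.0353, but adjusted p = 0.431 with an estimated correlation), with Csnk1d at 0.59, Per2 at 0.43 and Per1 at 0.32. The clock call (circadian clock genes, 0.5 h against naive) was lost without naive array 2 (adjusted p = 0.205), naive array 3 (0.0576), 0.5 h array 1 (0.198) or 0.5 h array 3 (0.115), with medians of 0.031 to 0.046, and its median was 0.14 without 0.5 h array 2.

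In the 0.5 h comparison 8 of 13576 probe sets passed, all 8 of them higher. At an unadjusted p of 0.05 there were 715, against 678.8 by chance, and the arrays of both groups did not overlap in 10.4% of probe sets, where chance gives 10%. The count was 4 without naive array 1, naive array 3, 0.5 h array 2 or 0.5 h array 3, and 5 without 0.5 h array 1. It was 16 with array weights, and it was 5 both with only the 2 groups in the model and without the 3 arrays of highest 18S signal.

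**Figure D1:**
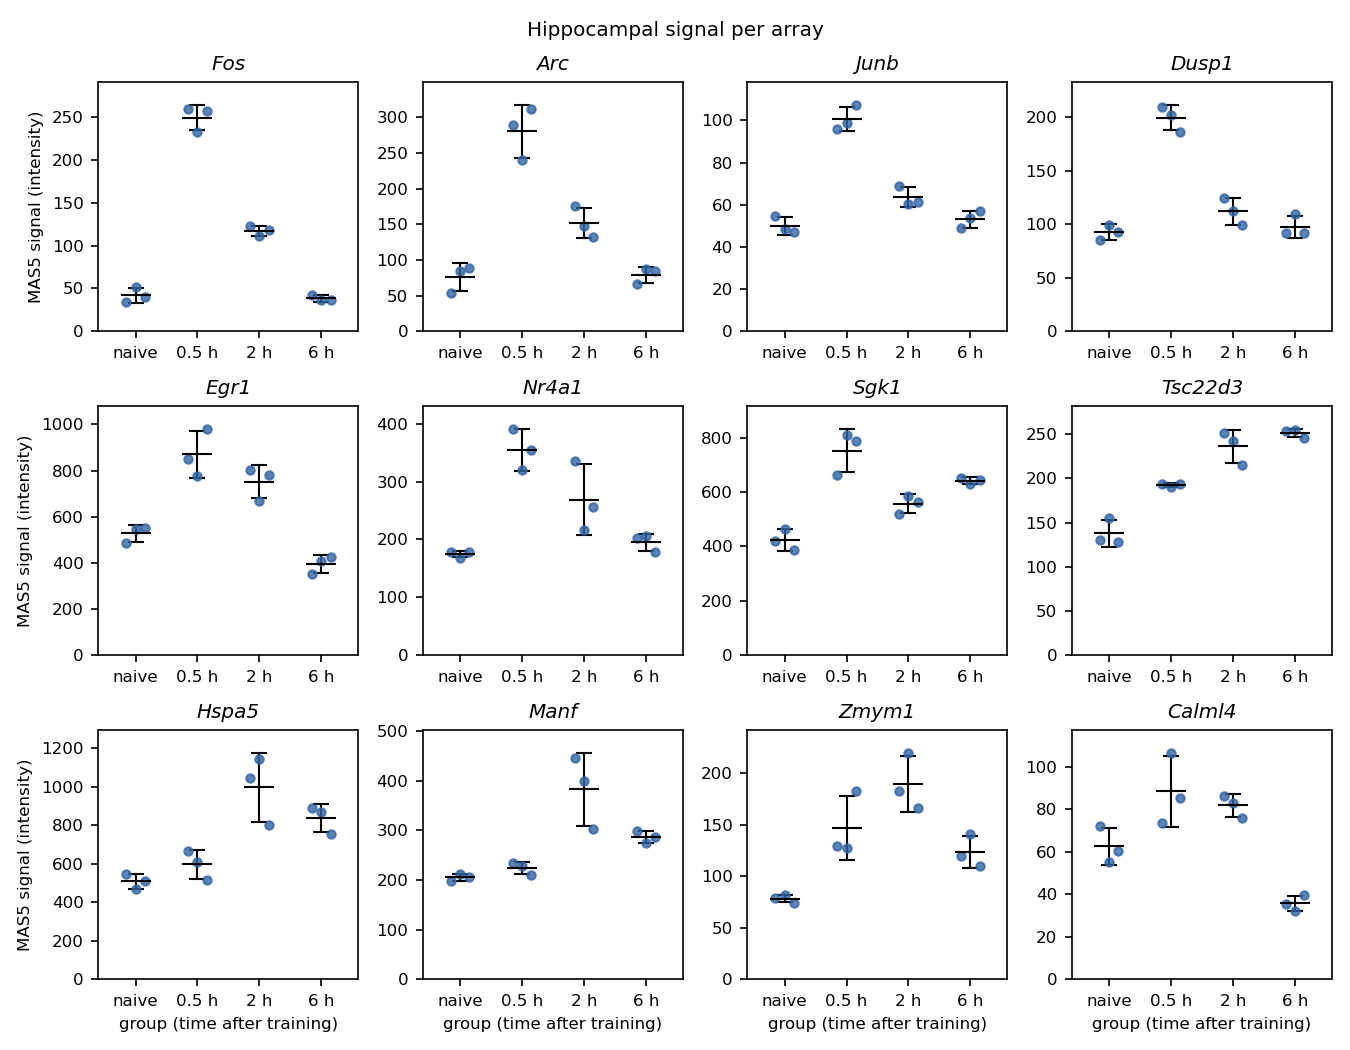
MAS5 signal (vertical axis, linear scale, arbitrary units) of 12 genes in the 4 groups (horizontal axis). Points are arrays, horizontal lines are means and bars are SDs of 3 arrays. All 3 arrays at 0.5 h lie above all 3 naive arrays for Fos, Arc, Junb, Dusp1, Egr1, Nr4a1, Sgk1, Zmym1, Tsc22d3 and Calml4. All 3 arrays at 2 h lie above the naive arrays for Hspa5 and Manf, and also for Zmym1 and Tsc22d3.

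The second comparison asked what differed from naive 2 h after training. Fos was still higher, at a signal of 117 ± 5.71 against 41.9 ± 8.71, or 2.76-fold (log2 change 1.46 ± 0.13, adjusted p = 0.00154). Chaperones of the endoplasmic reticulum appeared among the rises. Hspa5, the chaperone also called BiP, rose 1.94-fold, from 509 ± 38.9 to 998 ± 179 (log2 change 0.95 ± 0.14, adjusted p = 0.0452), and its second probe set rose by 0.86. Manf, a neurotrophic factor resident in that compartment, rose 1.84-fold, from 205 ± 6.32 to 383 ± 73.6 (log2 change 0.88 ± 0.12, adjusted p = 0.0389). Both calls depended on the settings: Hspa5 lost it in 19 of 25 (log2 change 0.84 to 1.11, adjusted p up to 0.669) and Manf in 18 of 25 (0.76 to 1.04, adjusted p up to 0.669). These include median centring, no filter, the 18S covariate and the removal of any array other than 2 h array 3, and for Hspa5 also no pseudocount and quantile normalization. Fos at 2 h lost its call in 2 of 25, without the 3 arrays of highest 18S signal and with only the 2 groups in the model (adjusted p up to 0.104).

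Tsc22d3, the glucocorticoid-induced leucine zipper gene, rose 1.71-fold at 2 h, from 138 ± 15.3 to 236 ± 18.5 (log2 change 0.77 ± 0.094, adjusted p = 0.0150). Its 2 other probe sets were at 0.27 and 0.59. Zmym1, a zinc finger gene, went from 78.3 ± 3.83 to 189.8 ± 27.3 (log2 change 1.25 ± 0.15, adjusted p = 0.0150). At 0.5 h Zmym1 was already at 0.87 and this probe set of Tsc22d3 at 0.48, neither past the threshold. Fubp1, which binds single-stranded DNA and regulates Myc, was the only fall, from 124 to 71.0 (log2 change -0.79 ± 0.099, adjusted p = 0.0151), but the mean of its 2 other probe sets was 0.049 ± 0.13. Arc was at 1.01 (adjusted p = 0.149), Nr4a1 at 0.59, Egr1 at 0.50, Sgk1 at 0.39, Junb at 0.34 and Dusp1 at 0.27, none past the threshold. The other genes of smallest unadjusted p were Crkl at 0.51 (adjusted p = 0.0902), Rpl39 at -0.71 (0.0604), Zfp810 at -0.56 (0.0779), Gpc4 at -0.59, Shmt1 at -0.78 and Pdgfrb at -0.71, again not past it. Bdnf was at -0.16 and Homer1 at 0.08. The calls of Tsc22d3 (9 of 25 settings, adjusted p up to 0.597), Zmym1 (9 of 25, up to 0.255) and Fubp1 (10 of 25, up to 0.255) were each lost with no filter and without naive array 1 or 3 or 2 h array 1 or 2, and those of Zmym1 and Fubp1 also without naive array 2.

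Lists of protein-folding genes had calls at 2 h with camera, which were lost with an estimated correlation. Of 20 cytosolic heat shock chaperones, 19 had positive changes (median 0.27, adjusted p = 1.81e-12, but adjusted p = 0.110 with an estimated correlation). In that list 0 passed in limma over all probe sets and 8 rose adjusted over the list alone. Hspa1b was at 1.15, Hspb1 at 0.80, Dnajb1 at 0.73 and Chordc1 at 0.49. Of 24 genes for endoplasmic reticulum chaperones and the unfolded protein response, 2 rose (Hspa5 and Manf) and 22 did not pass, with 7 rises adjusted over the list alone (median 0.31, adjusted p = 1.63e-08, but adjusted p = 0.110 with an estimated correlation). Pdia6, a disulfide isomerase, was at 0.63 and Xbp1, a transcription factor of the unfolded protein response, at 0.56. The 18S control was highest among the 2 h arrays in array 1, at 642.5.

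Activity-induced and glucocorticoid-responsive genes had calls at 2 h too. Of 23 activity-induced effectors, 0 passed in limma over all probe sets and 6 rose adjusted over the list alone (median 0.24, adjusted p = 6.09e-08, but adjusted p = 0.0575 with an estimated correlation), with Inhba, an activin subunit, at 0.92. The median of activity-induced effector genes, 2 h against naive, was 0.16 without 2 h array 1. Of 18 immediate-early transcription factors, Fos alone rose over all probe sets and 4 rose adjusted over the list alone (median 0.17, adjusted p = 7.06e-06, but adjusted p = 0.0575 with an estimated correlation). Of 23 glucocorticoid-responsive genes, 4 rose adjusted over the list alone, and over all probe sets 1 rose, Tsc22d3, by a probe set other than the brightest (median 0.15, adjusted p = 6.55e-06, but adjusted p = 0.0575 with an estimated correlation). Errfi1, which is also in the list of activity-induced effectors, was at 0.46 and Gjb6 at 0.35. The comparisons at 0.5 h and 2 h share their naive arrays, so they are not independent of each other.

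Lists of markers of cell types and regions had calls at 2 h too, again lost with an estimated correlation. The 11 choroid plexus markers had a median of 0.38 (adjusted p = 2.36e-06, but adjusted p = 0.179 with an estimated correlation), with Cldn2 at 0.78, Col8a1 at 0.57, Kl at 0.49 and Calml4 at 0.38, and no member past the threshold over all probe sets or adjusted over the list alone. The 7 dentate granule neuron markers had a median of -0.35 (adjusted p = 0.000384, but adjusted p = 0.175 with an estimated correlation), and 3 fell adjusted over the list alone. Among them Tdo2 was at -0.52, Dsp at -0.35 and Lct at -0.32. That median (dentate granule neuron markers, 2 h against naive) was -0.22 both without 2 h array 1, the 2 h array of highest 18S signal, and with the 18S covariate. The 9 endothelial and mural markers had a median of -0.19 (adjusted p = 0.00154, but adjusted p = 0.225 with an estimated correlation), and 1 fell adjusted over the list alone. The 7 thalamus markers had a median of 0.19 (adjusted p = 0.00294, but adjusted p = 0.114 with an estimated correlation), with Zic1 at 0.66.

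The 10 glutamate receptor genes had a median of -0.20 at 2 h (adjusted p = 0.0397, but adjusted p = 0.175 with an estimated correlation), with Grin2b at -0.66 and Gria1 at -0.22. This call (ionotropic and metabotropic glutamate receptors, 2 h against naive) was lost without naive array 1 (adjusted p = 0.0516), 2 (0.0545) or 3 (0.0680), 2 h array 1 (0.0815) or 2 (0.124), 0.5 h array 3 (0.0511) or 6 h array 3 (0.0535).

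In the 2 h comparison 7 probe sets passed, 6 higher and 1 lower, against 3 higher and 1 lower after median centring. At an unadjusted p of 0.05 there were 1149, and 13.8% of probe sets had arrays of both groups that did not overlap, where chance gives 10%. The count was 1 without naive array 1, naive array 3, 2 h array 1 or 2 h array 2, 2 without naive array 2, 4 without 0.5 h array 2 or 3 or any 6 h array, and 21 without 2 h array 3. It was 1 with no filter, 11 with the stricter filter, 2 with the 18S covariate, 1 without the 2 arrays of highest 18S signal, and 0 both without the 3 arrays of highest 18S signal (868 at an unadjusted p of 0.05) and with only the 2 groups in the limma model (1087).

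The third comparison asked what differed from naive 6 h after training. Tsc22d3 was the only gene past the threshold, at 251 ± 4.63 against 138 ± 15.3, or 1.82-fold (log2 change 0.86 ± 0.094, adjusted p = 0.0144). Its log2 change was 0.81 to 0.95 over the 25 other settings. Its call was lost in 10 of them, among them the 18S covariate and the removal of naive array 1 or 3 or any 6 h array. Sgk1 was at 0.60 (adjusted p = 0.0866). Fos, at -0.10, and Arc, at 0.09, lay near naive, and Egr1 was at -0.42 (adjusted p = 0.199). The other genes of smallest unadjusted p did not pass: Homer3, a postsynaptic scaffold gene, was at 0.59, Ak3 at 0.64, Abcc5 at 0.87 and Arih2 at 0.89. On the negative side were Slc17a6, a vesicular glutamate transporter, at -0.996, Adamts4 at -0.89, Arsg at -0.73, Fubp1 at -0.66, Phldb1 at -0.54 and Pdlim2 at -0.47, all with an adjusted p of 0.0846. Bdnf was at 0.0086, Homer1 at 0.03 and Fkbp5, a glucocorticoid-induced co-chaperone, at 0.31. Dbp, a clock output gene, was at -0.46 after -0.08 at 0.5 h and -0.20 at 2 h.

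Glucocorticoid-responsive genes rose as a group at 6 h, and this call held with an estimated correlation. Of 23 members 0 passed in limma by their brightest probe set, 1 (Tsc22d3) passed by any probe set, and 9 rose adjusted over the list alone (median 0.24, adjusted p = 1.63e-08, and adjusted p = 0.0337 with an estimated correlation). Mertk, a receptor for apoptotic debris, was at 0.48 and Slc2a1, a glucose transporter, at 0.38. Of 24 endoplasmic reticulum chaperone genes, 7 rose adjusted over the list alone (median 0.22, adjusted p = 2.05e-05, but adjusted p = 0.200 with an estimated correlation), with Hspa5 at 0.72, Pdia4 at 0.54, Pdia6 at 0.50 and Manf at 0.48. The median (endoplasmic reticulum chaperones and unfolded protein response, 6 h against naive) was 0.14 without 6 h array 2. Of 20 heat shock chaperones, 1 rose adjusted over the list alone (median 0.16, adjusted p = 2.6e-05, but adjusted p = 0.326 with an estimated correlation), with Hspb1 at 0.69. That median was 0.10 with the 18S covariate.

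Lists of choroid plexus and of oligodendrocyte markers had calls at 6 h with negative medians. The 11 choroid plexus markers had a median of -0.77 (adjusted p = 1.13e-07, but adjusted p = 0.1498 with an estimated correlation). Over all probe sets 0 passed in limma, and 9 fell adjusted over the list alone. Calml4 was at -0.77, Otx2, a homeobox gene, at -1.06, Sostdc1 at -0.89 and Folr1, a folate receptor, at -0.80. Ttr, which encodes the main secreted protein of choroid plexus, was at 0.09 at 6 h, 0.16 at 2 h and 0.10 at 0.5 h. The 11 oligodendrocyte markers had a median of -0.35 (adjusted p = 1.8e-06, but adjusted p = 0.1498 with an estimated correlation), and 5 fell adjusted over the list alone. With the 18S covariate the oligodendrocyte median was -0.25. The myelin genes Aspa at -0.46, Cnp at -0.42, Mog at -0.39 and Mag at -0.37 led that list. All 3 arrays at 6 h had an 18S control above every naive array, at 77.9 or more against 55.9 or less.

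Weaker lists at 6 h were the 21 postsynaptic density genes and the 45 ribosomal protein genes. The postsynaptic list had a median of 0.06 (adjusted p = 0.0307, but adjusted p = 0.528 with an estimated correlation), and 2 of its genes rose adjusted over the list alone, with Homer3 at 0.59 and Baiap2 at 0.36. Its call (postsynaptic density scaffolds and kinases, 6 h against naive) was lost without naive array 1 (adjusted p = 0.157), 6 h array 2 (0.184) or 6 h array 3 (0.0567) and with the 18S covariate (0.404), and without the 3 arrays of highest 18S signal the median was -0.030. Without naive array 1 or 3 its median was 0.042 or 0.10. The ribosomal list had a median of 0.05 (adjusted p = 0.0334, but adjusted p = 0.470 with an estimated correlation), with Rpl27a at 2.43 ± 0.64 and Rps27 at 1.16. Its call (cytosolic ribosomal proteins, 6 h against naive) was lost without naive array 3 (adjusted p = 0.0962) or 6 h array 2 (0.187, median 0.029), and after quantile normalization (0.683), where its median was -0.014; with the 18S covariate the median was 0.089.

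In the 6 h comparison 1 probe set passed, and at an unadjusted p of 0.05 there were 1441, of which 663 were higher and 778 lower. Arrays of both groups did not overlap in 20.4% of probe sets, where chance gives 10%. In limma the count was 0 without naive array 1, naive array 3, 6 h array 2 or 6 h array 3 (1033 to 1267 at an unadjusted p of 0.05), 1 different, lower probe set without 6 h array 1, and 2 without 2 h array 3. It was 3 with no filter, 17 with the stricter filter, 39 with a variance trend, 156 with array weights, and 0 with the 18S covariate (1060 at an unadjusted p of 0.05), without the 2 or 3 arrays of highest 18S signal (1182 and 684) or with only the 2 groups in the model (1843).

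**Figure D2:**
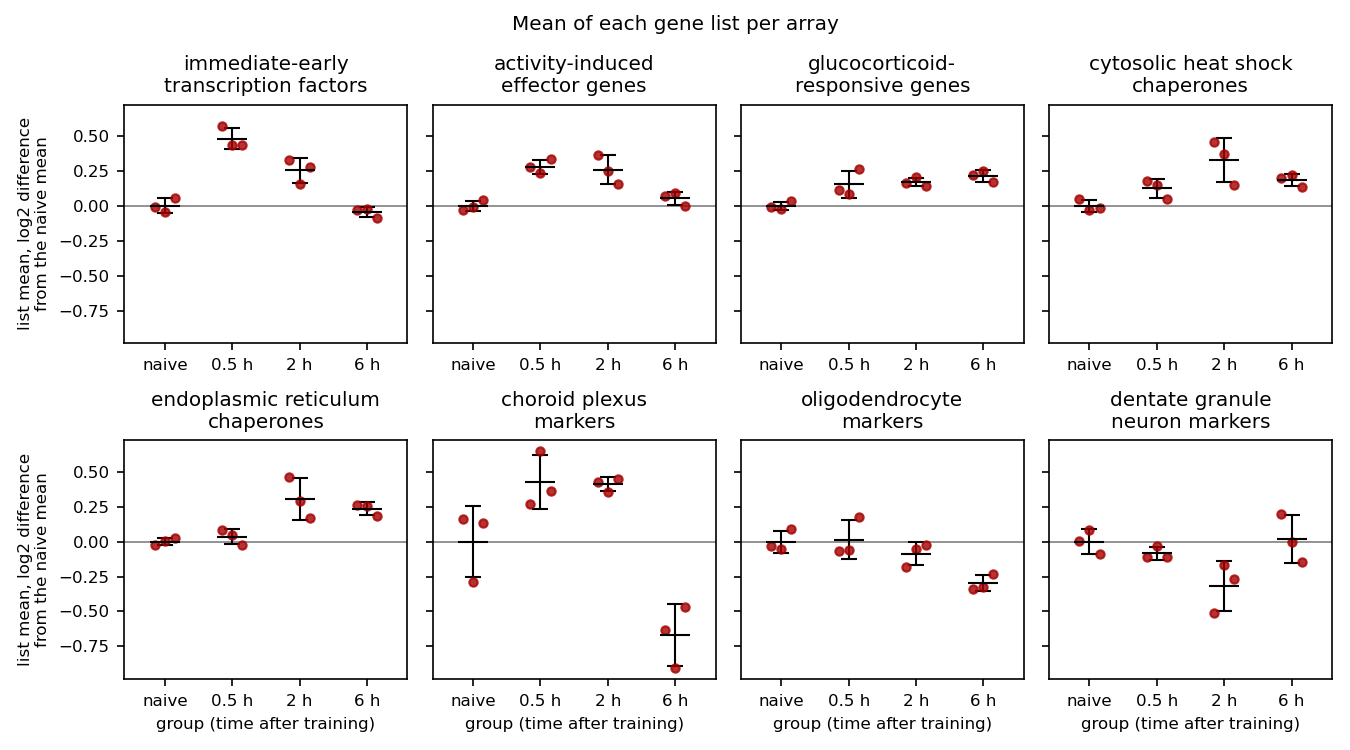
Mean log2 difference from the naive mean (vertical axis) of the members of 8 gene lists in each array of the 4 groups (horizontal axis). Points are arrays, and lines and bars are means and SDs of 3 arrays. Choroid plexus markers lie between -0.29 and 0.16 in naive arrays, between 0.27 and 0.65 at 0.5 h, between 0.36 and 0.45 at 2 h and between -0.91 and -0.47 at 6 h.

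The comparison of 2 h with 0.5 h tested how the early response changed. Fos fell by 1.07 ± 0.13 on the log2 scale, from 249 ± 14.5 to 117 ± 5.71 (adjusted p = 0.0402). Dusp1 was at -0.83 (adjusted p = 0.0537) and Junb at -0.65 (adjusted p = 0.0998), not past the threshold. Immediate-early transcription factors had a median of -0.22, with 1 of 18 fallen over all probe sets and 4 adjusted over the list alone (adjusted p = 0.000236, but adjusted p = 0.148 with an estimated correlation). Endoplasmic reticulum chaperones had a median of 0.19, with 7 rises adjusted over the list alone (adjusted p = 8.73e-09, but adjusted p = 0.148 with an estimated correlation), and heat shock chaperones a median of 0.17 (adjusted p = 1.32e-06, but adjusted p = 0.173 with an estimated correlation).

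Of 32 lists compared between 2 h and 0.5 h, 12 had a call and 0 kept it with an estimated correlation in camera. Fos was the 1 probe set past the threshold, and at an unadjusted p of 0.05 there were 838. Arrays of both groups did not overlap in 9.09% of probe sets, where chance gives 10%. The count was 0 in limma (621 to 1152 at an unadjusted p of 0.05) without naive array 3, any 0.5 h array, 2 h array 1, 2 h array 2 or any 6 h array, and 4 without 2 h array 3, with Fos not among them. It was also 0 with no pseudocount, no filter, either other normalization, the 18S covariate, the 2 or 3 arrays of highest 18S signal left out, or only the 2 groups in the model (548 to 1235).

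The comparison of 6 h with 2 h tested the later change, and 27 probe sets passed. Fos fell by 1.57 ± 0.13 on the log2 scale, to a signal of 38.4 ± 3.70 (adjusted p = 0.000725). Egr1 fell by 0.93 ± 0.12, from 751 ± 71.3 to 394 ± 38.2 (adjusted p = 0.00824). Of the other named falls, Aqp1, Cldn2 and Otx2 are choroid plexus markers and Zic1 is a thalamus marker. Kcne2, a potassium channel subunit in none of the marker lists, fell by 1.33 ± 0.17 (adjusted p = 0.00967). Against naive it was at 0.66 at 0.5 h, 0.62 at 2 h and -0.72 at 6 h. The choroid plexus marker Calml4 had a like course (0.48, 0.38 and -0.77), so the fall of Kcne2 cannot be told apart from that of those markers. Aqp1, a water channel, fell by 1.42 ± 0.23, Zic1, a zinc finger transcription factor, fell by 1.39 ± 0.23, Cldn2, a tight junction gene, fell by 1.38 ± 0.23, and Otx2 fell by 1.31 ± 0.22 (adjusted p = 0.0352 for the last 4). The calls of Fos, Kcne2 and Egr1 were lost in 1 of 25, 3 of 24 and 4 of 25 other settings, that of Fos without the 3 arrays of highest 18S signal (adjusted p = 0.213) and those of Kcne2 and Egr1 also without 2 h array 1 (adjusted p of each up to 0.331). The calls of Aqp1, Zic1, Cldn2 and Otx2 were lost in 12 to 15 settings (adjusted p up to 0.841), among them the removal of naive array 3, 0.5 h array 1 or any 2 h or 6 h array, and for Otx2 also 0.5 h array 2.

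Choroid plexus markers had a median of -1.16 from 2 h to 6 h, with 6 of 11 members fallen over all probe sets and 9 adjusted over the list alone (adjusted p = 2.23e-17, but adjusted p = 0.115 with an estimated correlation). Of 7 thalamus markers 2 fell, Zic1 and Slc17a6 (median -0.071, mean -0.40, adjusted p = 0.00843, but adjusted p = 0.155 with an estimated correlation). Oligodendrocyte markers had a median of -0.26, with 6 falls adjusted over the list alone (adjusted p = 3.27e-05, but adjusted p = 0.170 with an estimated correlation). Dentate granule neuron markers had a median of 0.41, with 3 rises adjusted over the list alone (adjusted p = 5.27e-05, but adjusted p = 0.154 with an estimated correlation). Rises past the threshold were Nrde2 at 0.66 ± 0.10, Homer3 at 0.56 ± 0.093 and Crocc, a gene of the ciliary rootlet, at 0.55 ± 0.09. Over the other settings their log2 changes were 0.54 to 0.74, 0.47 to 0.61 and 0.38 to 0.62, all positive. Their calls were lost in 12 of 24, 16 of 25 and 16 of 24 of those settings. All 3 were lost with the 18S covariate and without naive array 3, 2 h array 1 or 3 or 6 h array 2 or 3. The calls of Nrde2 and Homer3 were also lost without 6 h array 1. Those of Homer3 and Crocc were also lost without naive array 2, 0.5 h array 1 or 2 or 2 h array 2.

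Between 6 h and 2 h 27 probe sets passed, 3 higher and 24 lower, against 7 higher and 26 lower after quantile normalization. At an unadjusted p of 0.05 there were 1182, and 13.9% of probe sets had arrays of both groups that did not overlap, where chance gives 10%. The count was 5, 14 and 12 without 2 h array 1, 2 and 3, 14, 9 and 15 without 6 h array 1, 2 and 3, and 10 without naive array 3. It was 14 with no filter, 15 with the stricter filter, 13 with only the 2 groups in the model, 4 without the 2 arrays of highest 18S signal and 0 in limma without the 3 of highest 18S signal (657 at an unadjusted p of 0.05).

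Over all 4 groups the moderated F test found 30 probe sets, which named 25 genes, with Fos, Arc, Junb, Sgk1 and Tsc22d3 among them, and 1440 at an unadjusted p of 0.05. The 25 also held the choroid plexus markers Calml4, Otx2 and Sostdc1, the thalamus marker Slc17a6, and Kcne2, which were lower at 6 h than at 2 h. The 30 probe sets can therefore not all be read as a response to training. The count was 19 without naive array 1, 13 without naive array 3, and 19, 10 and 16 without 6 h array 1, 2 and 3. It was 16 with no filter, 63 with a variance trend, 76 with array weights, 10 without the 2 arrays of highest 18S signal and 1 without the 3 of highest. Of 96 list tests against naive 24 had a call with camera, and 3 of them kept it with an estimated correlation.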

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

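The tests of choroid plexus tissue, of Ttr, of the Fubp1 probe sets and of other splits of the arrays were chosen only after the results were seen, and so were the models with the 18S signal as a covariate or without the arrays of highest 18S signal, and the criterion by which the 18S test of the chaperones was read.

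Among the genes named in the text, those whose change from naive differed between times, by the limma test of the difference itself, were the following. From 0.5 h to 2 h Fos had a log2 change of -1.07. From 2 h to 6 h Fos had -1.57, Egr1 -0.93, Aqp1 -1.42, Cldn2 -1.38, Zic1 -1.39, Calml4 -1.16, Otx2 -1.31, Slc17a6 -1.24, Sostdc1 -1.15, Kcne2 -1.33 and Folr1 -1.30. On the positive side Homer3 had 0.56, Crocc 0.55 and Nrde2 0.66.

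Control probe sets, which were left out of the tested ones, gave values above those of every naive array in some trained arrays. The 18S ribosomal RNA control was at 642.5 in 2 h array 1, 77.9 in 6 h array 1, 177.6 in 6 h array 2 and 686.6 in 6 h array 3, against 55.9 at most in naive arrays. The median log2 difference of the spike-in controls from naive was 0.35 and 0.36 in 0.5 h arrays 1 and 3, 0.39 and 0.28 in 2 h arrays 2 and 3, and 0.32 and 0.16 in 6 h arrays 2 and 3, against 0.074 at most in naive arrays. The ratio of the 3' to the 5' actin control was 1.78 in 2 h array 2, against 1.59 at most in naive arrays.

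Choroid plexus markers were lower at 6 h than at 2 h, with a median of -1.16 and 6 of 11 members fallen, although the call of the list was lost with an estimated correlation (adjusted p = 0.115). With the 18S signal as a covariate the median was -1.22 ± 0.12 (bootstrap SE over members), which argues against RNA carry-over tracked by that signal as the whole cause. Within groups the members other than Ttr varied together from array to array. Their mean pairwise correlation was 0.357, against a 95th percentile of 0.106 in matched random lists. Markers regulated together would also vary so, and a correlation within groups does not measure the change between groups. Unequal amounts of choroid plexus in the dissected tissue may account for the change, but this test cannot decide it. Ttr, the most abundant transcript of that tissue, was at -0.075 ± 0.11 against a median of -1.23 for the other members. Unequal amounts of tissue should have moved it too, but its 3 probe sets rank 2, 5 and 7 of 22690 by mean signal. Near-saturation at such signals could hide a change. It was inferred from rank alone and not tested, so whether the share of Ttr moved is undecided. A response of choroid plexus to the time since training was not tested apart from unequal amounts of tissue and stays open.

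The lists of endoplasmic reticulum and heat shock chaperones had medians of 0.31 and 0.27 at 2 h against naive, and both calls were lost with an estimated correlation (adjusted p = 0.110 for each). The explanations below were tested on the endoplasmic reticulum list alone, so the arguments do not cover the heat shock list. The endoplasmic reticulum list was still at 0.22 ± 0.069 (bootstrap SE over members, not between arrays) at 6 h, when choroid plexus markers were at -0.77. As a log2 difference from the naive mean, its list mean was 0.18 to 0.26 in the 6 h arrays and -0.028 to 0.024 in naive arrays. Both argue against carried-over choroid plexus as the cause at 6 h, although the list's call at 6 h was also lost with an estimated correlation. They do not bear directly on 2 h. Choroid plexus markers had medians of 0.45 at 0.5 h and 0.38 at 2 h, calls also lost with an estimated correlation. The endoplasmic reticulum list had a median of 0.020 at 0.5 h, with list means of -0.022 to 0.083 in those arrays. This argues against carried-over choroid plexus as the whole cause at 2 h. The lowest median of the endoplasmic reticulum list at 2 h without 1 naive or 2 h array was 0.21, which argues against a single array as the whole cause. The list mean was 0.46, 0.29 and 0.16 in 2 h arrays 1, 2 and 3, so it was highest in the 2 h array of highest 18S signal. The 18S covariate moved the dentate granule median at 2 h from -0.35 to -0.22. With it the endoplasmic reticulum median at 2 h was 0.29 ± 0.09 (bootstrap SE over members, camera adjusted p = 7.91e-07 at the preset correlation). Without the 2 arrays of highest 18S signal it was 0.26 (1.14e-05). At the preset correlation these values argue against RNA carry-over tracked by that signal as the whole cause. The bootstrap error leaves room for a part, and the stricter bound set before the result was seen was not met. With that covariate Hspa5 (0.95 ± 0.14 to 0.96 ± 0.16) and Manf (0.88 ± 0.12 to 0.82 ± 0.13) lost their calls at 2 h, Hspa5 with no smaller change but a larger error and Manf with both a smaller change and a larger error. A response to training, to handling or to the time of collection may also underlie it, and none of these was tested, since the labels name no handled or time-matched control.

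The Fubp1 probe set was lower at 2 h while the gene's 2 other tested probe sets were at a mean of 0.049 ± 0.13. The difference between them was -0.84 ± 0.16, a test that restates the pattern it was chosen from. The fall was seen in that probe set alone. A transcript variant and cross-hybridization could each give it, and nothing measured here separates them.

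Other splits of the arrays were also counted. In the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 8 and 0 at 0.5 h, 7 and 4 at 2 h, 1 and 0 at 6 h, 1 and 0 between 2 h and 0.5 h, and 27 and 0 between 6 h and 2 h. For the F test over the 4 groups 1 of 100 splits, the real one, gave as many probe sets (30, against 13 in the highest other). This argues against chance in the spread between these arrays but does not exclude it. The 30 probe sets include choroid plexus markers, so their number does not measure a response to training alone. The labels do not say whether the arrays held separate pools, and splits of arrays cannot show differences between pools.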

How the results depend on the processing

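The alternatives with the 18S covariate and with 2 or 3 arrays of highest 18S signal left out were chosen only after the data were seen. Fos, Arc, Dusp1 and Junb at 0.5 h stayed past the threshold in all 25 other settings, from log2 2.39 to 2.69, 1.66 to 2.02, 1.03 to 1.15 and 0.91 to 1.05. Fos at 2 h did so in all but 2 and Fos from 2 h to 6 h in all but 1, while Hspa5 failed in 19 and Manf in 18 of 25. Of 26 results of a named gene in a comparison past the threshold 0 reversed, and those that kept their call numbered 5 to 26 by setting. Of 24 calls of a list in a comparison 20 to 24 were kept in refits, 13 with fry and 3 with an estimated correlation, and 0 turned. Scaling moved the median change of all probe sets by less than 0.03.

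Counts that moved are given by setting, and the cause was not tested except that some settings hold fewer arrays or other numbers of tests. No pseudocount gave 0 from 0.5 h to 2 h, and the higher one gave 2. No filter gave 1 at 2 h, 3 at 6 h, 0 from 0.5 h to 2 h, 14 from 2 h to 6 h and 16 in the F test. The stricter filter gave 11 at 2 h, 17 at 6 h, 3 from 0.5 h to 2 h and 15 from 2 h to 6 h. Quantile normalization gave 0 from 0.5 h to 2 h, and median centring gave 4 at 2 h and 0 from 0.5 h to 2 h. The variance trend gave 39 at 6 h, 3 from 0.5 h to 2 h and 63 in the F test. Array weights gave 16 at 0.5 h, 156 at 6 h, 2 from 0.5 h to 2 h and 76 in the F test. An adjusted p of 0.1 gave 14 at 2 h, 26 at 6 h, 3 from 0.5 h to 2 h, 52 from 2 h to 6 h and 69 in the F test. An unadjusted p of 0.05 with a 1.5-fold change gave 64, 128, 189, 101 and 142 in the comparisons of 2 groups, in the order 0.5 h, 2 h, 6 h, 0.5 h to 2 h and 2 h to 6 h.

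Settings with fewer arrays leave fewer degrees of freedom. Only the 2 groups in the model gave 5, 0, 0, 0 and 13 in that order. Without the 2 arrays of highest 18S signal the counts were 1 at 2 h, 0 at 6 h, 0 from 0.5 h to 2 h, 4 from 2 h to 6 h and 10 in the F test. Without the 3 highest they were 5, 0, 0, 0 and 0 in that order and 1 in the F test, and a group left with 1 array is assumed to vary like the others. The 18S covariate gave 2 at 2 h, 0 at 6 h and 0 from 0.5 h to 2 h. Leaving out each array in turn gave 4 to 8 at 0.5 h, 1 to 21 at 2 h, 0 to 2 at 6 h, 0 to 4 from 0.5 h to 2 h, 5 to 30 from 2 h to 6 h and 10 to 33 in the F test. In the 30 combinations of a comparison and a setting where limma gave 0, the number at an unadjusted p of 0.05 was 548 to 1843.

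The replicate number as a block gave 7 at 0.5 h, 5 at 2 h, 0 at 6 h, 0 from 0.5 h to 2 h, 10 from 2 h to 6 h and 18 in the F test. The numbers did not pair the arrays: after group means were removed, the correlation of 18 pairs of arrays with the same number was -0.26 to 0.23 (mean -0.038, against 0.0196 for different numbers), and 2 of 12 arrays were closest to one of their own number. Signal over background limits all of this, since dim probe sets were left out and most changes of log2 0.5 were missed in simulated data.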

Other observations

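The list tests between times were chosen only after the data were seen, and the correlation of oligodendrocyte with choroid plexus markers was chosen after both lists were seen to have negative medians at 6 h. Many groups of neuronal genes had no call at any time against naive. Median log2 changes at 0.5 h, 2 h and 6 h were 0.018, 0.019 and 0.039 for 23 synaptic vesicle genes, 0.071, -0.021 and -0.076 for 12 GABA genes, 0.017, -0.056 and 0.022 for 35 voltage-gated channels, -0.030, 0.030 and 0.015 for 23 cAMP, MAPK and CREB signalling genes, 0.00047, -0.061 and -0.046 for 29 adhesion and guidance genes, and -0.011, -0.12 and -0.052 for 18 neurotrophin and growth factor genes. Chromatin regulators, 22 genes, were at 0.0041, -0.00098 and 0.012. Markers of CA1 neurons (4 genes) were at 0.026, -0.19 and -0.10, of CA3 neurons (6 genes) at -0.031, 0.015 and 0.035, of interneurons (12 genes) at -0.025, 0.046 and -0.037, and of striatum (5 genes) at 0.053, 0.23 and -0.16.

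Glial and housekeeping groups without a call had these medians. In the same order of times, 14 astrocyte markers were at -0.019, 0.021 and 0.089, 13 microglia markers at -0.084, -0.089 and -0.0017, 6 oligodendrocyte precursor markers at 0.019, -0.14 and -0.045, and 8 meningeal and fibroblast markers at -0.026, 0.088 and -0.077. The 34 proteasome and ubiquitin genes were at -0.028, -0.017 and -0.016, the 20 cholesterol synthesis genes at 0.027, 0.048 and -0.031, and the 71 oxidative phosphorylation subunits at -0.033, 0.014 and 0.0071. The smallest adjusted p among these 18 lists was 0.0599, for the striatum markers at 2 h. A p that misses the threshold does not show that a group was unchanged.

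Between times, lists with a call in camera that have not been described above all lost it with an estimated correlation. From 0.5 h to 2 h they were glutamate receptors (median -0.12), ribosomal proteins (0.046), oxidative phosphorylation (0.051), oligodendrocytes (-0.12), their precursors (-0.12), thalamus (0.18), striatum (0.21), dentate granule neurons (-0.17) and CA1 neurons (-0.19), with adjusted p from 0.170 to 0.357 under an estimated correlation. From 2 h to 6 h they were activity-induced effectors (-0.18), immediate-early transcription factors (-0.21), glutamate receptors (0.15), heat shock chaperones (-0.12), channels (0.061), microglia (0.18), endothelial and mural cells (0.18) and striatum (-0.38), with adjusted p from 0.148 to 0.384 under an estimated correlation.

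Oligodendrocyte and choroid plexus markers had negative medians at 6 h against naive, but both calls were lost with an estimated correlation (adjusted p = 0.1498 for each). In limma 0 members of either list passed over all probe sets, and 6 and 9 were lower at an unadjusted p of 0.05. The same difference in dissected tissue might underlie both medians. If so, both lists should vary together among the arrays of a group. Across the 12 arrays, as deviations from their group means, Pearson's r was 0.173 (p = 0.615, adjusted 0.652) and Spearman's rho was 0.161 (p = 0.652, adjusted 0.652), from 100000 permutations within groups, two-sided. Without the 2 arrays farthest from the median, r was -0.014. The result decides neither way.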
